A study of Mus musculus with 7 samples.

How the data were processed

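Total RNA of 4 mouse aortas and 3 cultures of bone marrow-derived macrophages was measured with a panel of quantitative PCR assays for microRNAs (miRNAs). The labels call each sample a biological replicate. The macrophages had been cultured for 7 days and polarized to the M1 (inflammatory) state with 100 ng/ml lipopolysaccharide for 14 hours and 10 ng/ml interferon-γ for 6 hours, per the labels' protocols. All mice were female. The labels give the strain of the aortas as apoE-/- and that of the macrophages as C57BL/6, so strain and sample type cannot be told apart. The series title describes the aortas as normal, so the strain label of the aortas is uncertain. RNA was isolated with a kit that keeps small RNAs, per the labels' protocols. The instrument, the threshold setting and any preamplification are not given in the sources used here.

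The authors' deposited raw values are cycle thresholds (Ct), the PCR cycle at which an assay crossed its threshold, so that a lower Ct stands for more target. The table holds 524 assays, of which 517 are for mouse miRNAs and 7 are controls (MammU6, snoRNA135, snoRNA202, snoRNA429, U87, Y1 and a plant miRNA with no mouse counterpart). Wells that did not cross are listed at Ct 40, which holds for 21.6% of the miRNA wells. The authors' deposited second table is on a log2 scale (differences in Ct). Its values equalled each Ct minus the sample's mean over the wells of MammU6 and snoRNA202, with a largest departure of 5e-05 cycles. That reading comes from the values themselves. Over 35 pairs of repeated wells the median difference was 0.46 cycles and the largest was 3.22 cycles.

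A well at Ct 35 or earlier was taken as detected, and later wells were set to 35. The scaled level of a miRNA was the sample's mean Ct over the 296 miRNAs detected in all 7 samples, minus the miRNA's Ct. It is on a log2 scale only if each cycle doubles the product, which was not measured, so folds rest on that assumption. A miRNA was tested if it was detected in at least 3 samples of either group, which held for 429. The groups were compared with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with group as the only term, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Where a miRNA was detected in no sample of a group, the fold is a lower bound, given as "at least". Where only some samples of a group detected it, the other wells entered at the limit, so the fold depends on the limit, and the number of samples is given. Where leaving out 1 sample moved a called difference by over 1.5-fold, the log2 difference without that sample is given. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01, for the 17 lists with at least 3 tested members, with p adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the tables and plots.

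The depth of a sample is given by how many miRNAs were detected and by its mean Ct, and 7 samples limit the precision. The test was tried on 20 simulated data sets of this comparison, with 479 miRNAs tested on average and 120 changed. The data had 429 tested. Simulated levels of undetected miRNAs lay around the limit, so noise let some of them count as detected. The shares below therefore may not carry over exactly to the data. It recovered 4.78% of changes of 1 on the log2 scale, 38.1% of changes of 2 and 72.7% of changes of 4, and 5.04% of its calls were false on average. A miRNA that did not pass may therefore still differ. The simulated changes went up as often as down and were at most 4 on the log2 scale, with noise independent between miRNAs. The share of false calls thus does not cover calls that depend on the choice of scaling.

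The groups, tests, lists, alternatives and the rule for naming miRNAs were set before the data were examined. The rule named the 10 largest differences in each direction among miRNAs past the threshold and detected in all 7 samples, up to 5 per direction among those detected in every sample of 1 group and in none of the other, up to 4 members of each list with the largest absolute difference, and always miR-155, miR-146a, miR-342-5p, miR-223, miR-142-3p, miR-21, miR-143, miR-145 and miR-126-3p. It gave 75 miRNAs. Others in the text were chosen after their values were seen. The lists cover haematopoietic, lipopolysaccharide-inducible, alternative activation, smooth muscle, striated muscle, endothelial, fibroblast, adipose, epithelial, neural, erythroid, lymphocyte, liver and gut, let-7, miR-17~92, Dlk1-Dio3, Sfmbt2 and testis miRNAs. They share members, and the erythroid list had 2 measured members, too few for a test. A further 7 lists were added after the data were seen. Star strands were counted as their own miRNA. Assays for near-identical family members (let-7, miR-133a and miR-133b, miR-17 and miR-106a) can pick up each other's target, so differences between such members are uncertain. Names were matched to mouse miRNA genes in RefSeq (GRCm38.p6) for 504 of the 517 assays. The files name no genome build, so no coordinates are given.

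Alternatives were scaling to snoRNA135 and snoRNA202, to the median, by quantiles, to MammU6, or not at all, the authors' deposited values, limits at Ct 32 and 38, detection in all 7 samples, no filter, a mean-variance trend with a robust prior, an exact permutation per miRNA, leaving out each replicate, and a replicate block. Added after seeing the data were a limit at Ct 28, leaving out early wells (before Ct 15 and at least 5 cycles before every other sample of the group), and leaving out aorta 3 and macrophage 3 together.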

Results

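miRNA levels were measured in 4 aortas and in 3 cultures of M1 macrophages, to set the miRNA profile of inflammatory macrophages against that of aortic tissue. The aortas held more detectable miRNAs. Of 517 miRNAs, 437 ± 19.4 (SD, n = 4) were detected per aorta and 350.3 ± 21.4 (SD, n = 3) per macrophage sample. The lowest aorta had 416 and the highest macrophage sample had 366. The mean Ct over the 296 miRNAs detected in every sample was 23.6 ± 0.86 (SD, n = 4) in aorta and 26.2 ± 1.35 (SD, n = 3) in macrophages, so the macrophage samples gave less signal. Macrophage replicate 3 had the latest mean Ct, at 27.8.

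**Figure D1:**
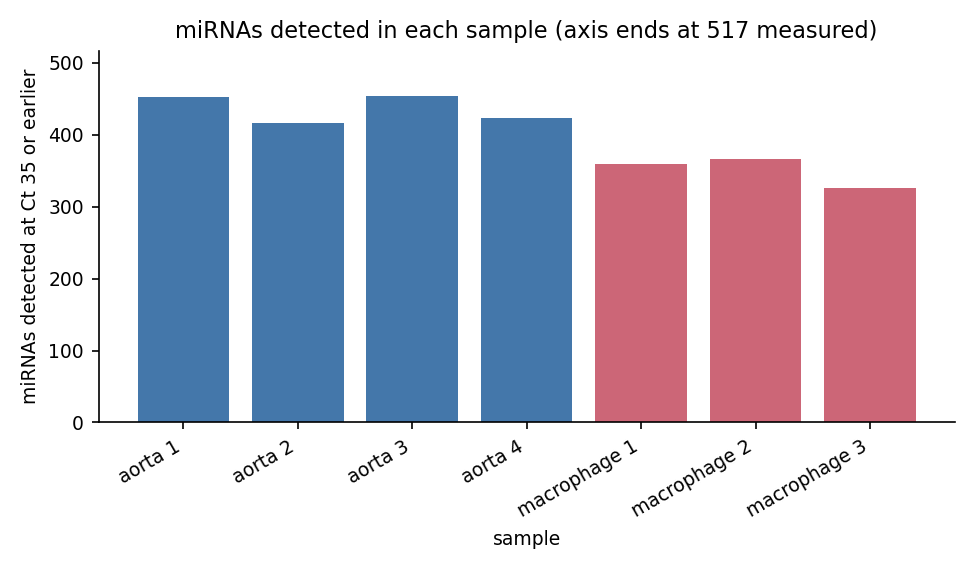
Bars give the number of miRNAs detected at Ct 35 or earlier (vertical axis, out of 517 measured) in each of the 4 aortas (blue) and 3 macrophage samples (red). The aortas range from 416 to 454 and the macrophage samples from 326 to 366.

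The profiles of the sample types stood apart. Across the 296 miRNAs, which are not independent replicates, Pearson's r averaged 0.945 between aortas (0.927 to 0.963), 0.932 between macrophage samples (0.922 to 0.944) and 0.503 between an aorta and a macrophage sample (0.467 to 0.543). Of 429 miRNAs tested, 238 differed between the groups (limma, adjusted p under 0.05), 106 of them higher and 132 lower in macrophages. At an unadjusted p under 0.05 the count was 255. The split between higher and lower depended on the scaling. It was 32 higher and 231 lower with scaling to snoRNA135 and snoRNA202, 157 and 108 with quantile normalization, 53 and 155 with the authors' deposited values, 52 and 124 with scaling to MammU6, and 10 and 207 without scaling. These settings shifted the median difference by -2.24, 0.76, -0.99, -0.66 and -2.64 on the log2 scale. The deposited values, counted among the scalings, also keep wells later than Ct 35 at their own Ct, with uncrossed wells at Ct 40. Under all 5 other scalings, the unscaled values left aside, 134 miRNAs kept their call, 31 of them higher and 103 lower. Folds are given relative to the miRNA mean and move with these shifts.

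Some of the reference small RNAs also differed between the groups. Relative to the miRNA mean, snoRNA135 was at 1.96 ± 0.55 (SD, n = 4) in aorta and 5.11 ± 0.07 (SD, n = 3) in macrophages. The values were 7.42 ± 0.12 and 8.75 ± 0.12 for snoRNA202, 1.15 ± 0.42 and 2.94 ± 0.27 for U87 and 0.32 ± 1.32 and 2.98 ± 0.86 for Y1. MammU6, at 9.79 ± 0.96 and 10.45 ± 0.39, differed by less than the SD of the aortas, and snoRNA429 was near one level at 7.03 ± 0.27 and 6.98 ± 0.06. These differences are relative to the miRNA mean and move with the scaling.

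Several miRNAs that rise after lipopolysaccharide were higher in macrophages relative to the miRNA mean, though as a list they missed the threshold. No unstimulated macrophages were measured, so a response to lipopolysaccharide cannot be told apart from a difference between macrophages and aortic tissue. miR-155, which promotes inflammatory signalling, was 144-fold higher (log2 difference 7.17 ± 0.66 SE, adjusted p = 0.000112). miR-146a, a brake on Toll-like receptor signalling, was 23.6-fold higher (4.56 ± 0.71 SE, adjusted p = 0.00138). miR-21 was 19.2-fold higher and miR-222 was 22.1-fold higher. Without scaling miR-146a, miR-21 and miR-222 missed the threshold (adjusted p = 0.235, 0.2003 and 0.165). miR-147, detected in 3 aortas, was 201-fold higher (adjusted p = 0.0107). It did not pass with the authors' deposited values (adjusted p = 0.0646), nor without aorta 3 and macrophage 3 together (adjusted p = 0.0674), a setting chosen after seeing the data. Without aorta replicate 2, 3 or 4 or macrophage replicate 1, miR-147 was at 9.08, 6.88, 6.46 and 8.31, against 7.66 on the log2 scale. Without macrophage replicate 1 miR-155 was at 6.49, and without macrophage replicate 3 miR-155 was at 7.89 and miR-146a at 5.54. Of the 11 tested miRNAs known to rise after lipopolysaccharide, 7 were higher, 2 were lower and 2 did not pass, and the counts adjusted over the list alone were also 7 and 2. The counts were 5 and 3 with scaling to the snoRNA pair, 4 and 2 with the authors' deposited values, 5 and 2 with MammU6, and 2 and 3 without scaling, where the median was -0.25 against 2.39 in the main setting. The lower members were miR-132 at -2.33 and miR-9 at -3.02 (-2.35 without macrophage replicate 1), both also known from nerve cells. The list test gave an adjusted p of 0.05995 (camera), and adjusted p = 0.473 with an estimated correlation. The list passed without macrophage replicate 3 (adjusted p = 0.0399), without aorta replicate 2 (adjusted p = 0.0428), with the snoRNA pair (adjusted p = 0.0192), the deposited values (adjusted p = 0.0259), MammU6 (adjusted p = 0.024), no scaling (adjusted p = 0.0171) and a limit of Ct 38 (adjusted p = 0.0487). Camera sets a list against the other miRNAs. The pass without scaling, at a median of -0.25, thus does not mean that the list was higher in macrophages than in aorta. With an estimated correlation the list missed the threshold in each of these settings (adjusted p from 0.351 to 0.795).

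White blood cell miRNAs went both ways. miR-223, a miRNA of myeloid cells, was 24.6-fold higher in macrophages (4.62 ± 0.53 SE, adjusted p = 0.000291). miR-142-3p was higher by 4.32 and miR-142-5p by 3.98 on the log2 scale. Without scaling miR-223, miR-142-3p and miR-142-5p missed the threshold (adjusted p = 0.1009, 0.137 and 0.312). miR-150, abundant in mature lymphocytes, was 102-fold lower (-6.67 ± 0.69 SE, adjusted p = 0.000187). miR-342-5p was at -3.62 ± 1.29 (SD, n = 4) in aorta and -1.85 ± 4.67 (SD, n = 3) in macrophages, a difference that did not pass (1.78 ± 2.01 SE, adjusted p = 0.497). It was not detected in macrophage replicate 3, and without that sample it was 4.57 higher (adjusted p = 0.00573). With scaling to the snoRNA pair the difference was -0.46. Of the 8 haematopoietic miRNAs, 4 were higher, 1 was lower and 3 did not pass, the same counts as adjusted over the list alone. Without scaling none was higher and 1 was lower. The list test did not pass (adjusted p = 0.127, and adjusted p = 0.473 with an estimated correlation), except without macrophage replicate 3 (adjusted p = 0.0197, and adjusted p = 0.276 with an estimated correlation) and in the settings given in the closing section.

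Further miRNAs were higher by large factors. miR-221, an abundant vascular miRNA that shares a seed with miR-222, was 47.9-fold higher in macrophages (5.58 ± 0.43 SE, adjusted p = 5.3e-05). miR-7a was 48.2-fold higher, miR-692 was 115-fold higher, miR-130b* was 70.9-fold higher and miR-135a* was 54.8-fold higher (adjusted p = 0.08005 without scaling). miR-699, miR-715 and miR-685 were 62.3-fold, 62.1-fold and 45.8-fold higher, with an adjusted p of 0.125 for miR-699 without scaling. miR-699 was at 4.70, 6.77 and 6.64 without aorta replicates 2, 3 and 4, against 5.96. Without aorta replicate 2 miR-692 was at 6.07 and miR-135a* at 4.90, and without aorta replicate 4 miR-135a* was at 6.53. The miR-699, miR-715 and miR-685 assays matched no miRNA gene in RefSeq, and what they detect is uncertain. miR-124 had the largest difference among the higher miRNAs past the threshold and detected in all 7 samples, at 8.10 ± 2.93 SE (adjusted p = 0.0486). It rested on 1 well of macrophage replicate 1 at Ct 9.1. Without that sample the difference was 4.43 (adjusted p = 0.0783). It was 9.95 and 10.05 without macrophage replicates 2 and 3, and 9.13 and 6.93 without aorta replicates 2 and 4. It also missed the threshold without aorta replicate 1, 3 or 4 (adjusted p = 0.0601, 0.0811 and 0.0897), with scaling to the snoRNA pair (adjusted p = 0.114), with the deposited values (adjusted p = 0.0869) and without scaling (adjusted p = 0.115).

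**Figure D2:**
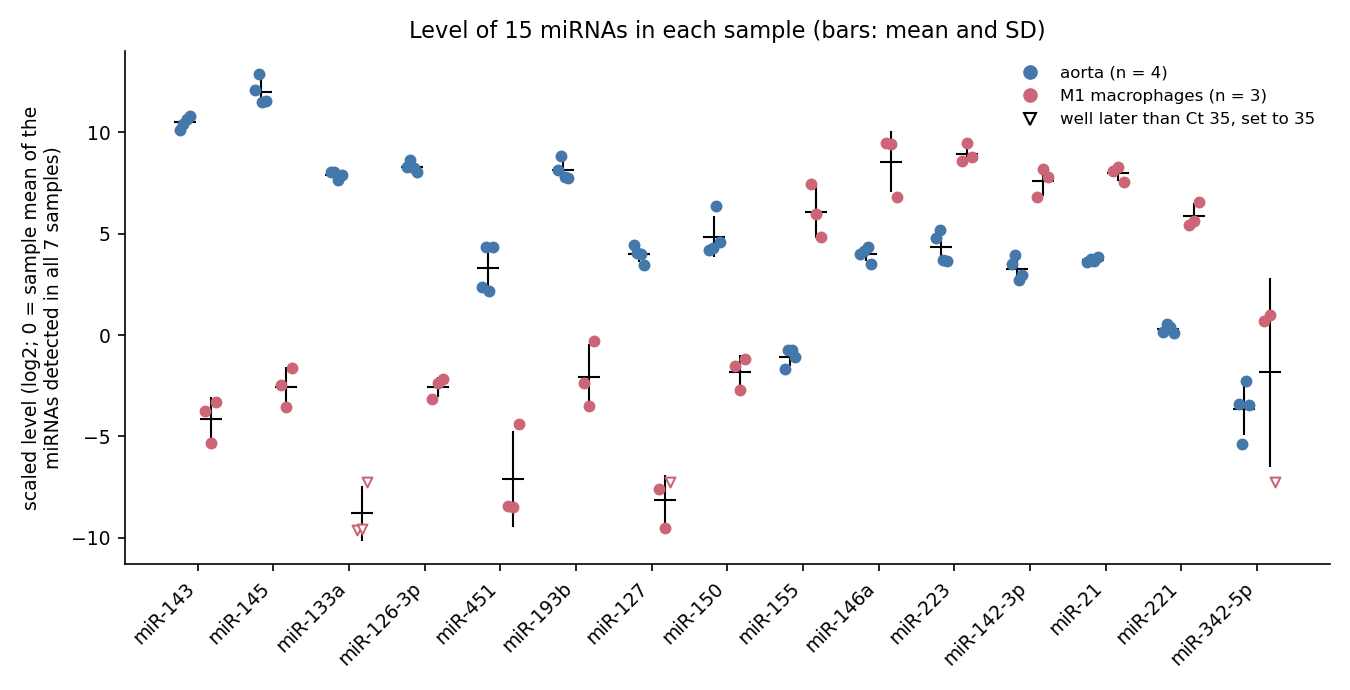
Points give the scaled level (vertical axis, log2, relative to the sample's mean over the miRNAs detected in all 7 samples) of 15 miRNAs in each aorta (blue, n = 4) and macrophage sample (red, n = 3), with bars for the mean and SD. Open triangles are wells later than Ct 35. miR-143 lies near 10.49 in aorta and -4.13 in macrophages, and miR-155 near -1.08 and 6.09.

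Among the named miRNAs, the largest lower differences were those of miR-133a, miR-143 and miR-145, all on the smooth muscle list. miR-133a is also on the striated muscle list. miR-143 was 25200-fold lower in macrophages (-14.62 ± 0.56 SE, adjusted p = 3e-06) and miR-145, transcribed with it and needed for the contractile state of smooth muscle, was 23800-fold lower (-14.54 ± 0.60 SE). miR-133a, a miRNA of muscle, was detected in all 4 aortas and in no macrophage sample, and was at least 106000-fold lower. miR-133b was at least 2040-fold lower. With quantile normalization the bounds were 51400-fold for miR-133a and 868-fold for miR-133b. Without macrophage replicate 3 they lay at -17.38 and -11.68 on the log2 scale, and without macrophage replicate 2 miR-143 was at -13.99. Of 8 smooth muscle miRNAs 6 were lower, none was higher and 2 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.0028, and adjusted p = 0.163 with an estimated correlation). Of 5 striated muscle miRNAs, 3 of which are also in the smooth muscle list, 4 were lower and 1 did not pass. miR-1 was 55.7-fold lower and miR-206 was 33.0-fold lower (-5.05, and -4.35 without macrophage replicate 2). That list's adjusted p was 0.0422, and 0.218 with an estimated correlation. It did not pass without aorta replicate 2 (adjusted p = 0.1004) or 4 (adjusted p = 0.0625), with the snoRNA pair (adjusted p = 0.101), with the deposited values (adjusted p = 0.0804), with detection in all 7 samples (adjusted p = 0.303), or in 3 further settings given in the closing section.

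Endothelial miRNAs did not move together. miR-126-3p and miR-126-5p, both strands of the hairpin in the endothelial gene Egfl7, were 1860-fold and 1030-fold lower (-10.86 ± 0.40 SE and -10.00 ± 0.66 SE, the latter -9.21 without macrophage replicate 1). miR-10a was lower at -2.35. miR-221 and miR-222 were higher, as was miR-503 at 4.77 (adjusted p = 0.0213), which missed the threshold without macrophage replicate 2 (adjusted p = 0.0648) or 3 (adjusted p = 0.0612), with scaling to the snoRNA pair (adjusted p = 0.118) or MammU6 (adjusted p = 0.0525), with the deposited values (adjusted p = 0.0745) and without scaling (adjusted p = 0.311). miR-503 was at 3.51 and 5.64 without aorta replicates 2 and 3. Of 7 members 3 were higher and 3 lower, or 4 and 3 adjusted over the list alone. The list's median was 1.47 (-0.77 with the snoRNA pair and -1.18 without scaling) and its mean was -0.99, and the list test did not pass (adjusted p = 0.926, and 0.926 with an estimated correlation).

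Most of the mesenchymal miRNAs and all of the fat miRNAs tested were lower in macrophages. Of 11 fibroblast miRNAs 8 were lower, 1 was higher and 2 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.0271, and adjusted p = 0.163 with an estimated correlation). The list missed the threshold without aorta replicate 4 (adjusted p = 0.0549), with the deposited values (adjusted p = 0.0526), with detection in all 7 samples (adjusted p = 0.13), with the replicate block (adjusted p = 0.0564) and in 2 settings added after seeing the data. miR-10b, detected in 2 macrophage samples, was 796-fold lower, miR-218 was 704-fold lower, miR-214 was 267-fold lower and miR-199a-3p was 231-fold lower. All 6 adipose miRNAs were lower (camera, adjusted p = 0.00496, and adjusted p = 0.163 with an estimated correlation; 6 adjusted over the list alone). miR-193b, a miRNA of brown fat cells, was 1160-fold lower, miR-203 was 37.0-fold lower and miR-365 was 35.1-fold lower. miR-455, detected in 1 macrophage sample, was at -7.83 on the log2 scale with its undetected wells set to the limit, and at -12.16 with the deposited values. Leaving out macrophage replicate 1 gave -8.42 for miR-218, -8.68 for miR-10b and -8.74 for miR-455. Leaving out macrophage replicate 2 gave -10.90 for miR-10b, -6.77 for miR-455, -9.43 for miR-193b and -4.42 for miR-365, and leaving out macrophage replicate 3 gave -10.97 for miR-193b. Both red blood cell miRNAs were lower, miR-451 by 10.39 ± 1.16 SE on the log2 scale and miR-486, which no macrophage sample showed, at least 55.5-fold, or 20.5-fold with quantile normalization. miR-486 was at -7.00, -4.80 and -6.48 without aorta replicate 1, aorta replicate 4 and macrophage replicate 3, against -5.80, and miR-451 at -9.74, -9.66 and -11.65 without macrophage replicates 1, 2 and 3.

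The imprinted Dlk1-Dio3 region, which holds one of the largest mouse miRNA clusters, was mostly lower in macrophages. Of its 55 tested miRNAs 35 were lower, 2 were higher and 18 did not pass, and the counts adjusted over the list alone were 35 lower and 3 higher (camera, adjusted p = 8.41e-07, and adjusted p = 0.269 with an estimated correlation). miR-434-3p was 1330-fold lower and miR-376c was 850-fold lower. miR-127, detected in 2 macrophage samples, and miR-376b*, detected in 1, were at -12.12 and -10.21 with undetected wells set to the limit, and at -14.78 and -11.53 with the deposited values. The higher members, named after their values were seen, were miR-381 at 3.74 and miR-494 at 2.35. Neither passed with scaling to the snoRNA pair (adjusted p = 0.221 and 0.837), with the deposited values (adjusted p = 0.0953 and 0.0745) or without scaling (adjusted p = 0.479 and 0.811), and miR-494 did not with MammU6 (adjusted p = 0.155). miR-381 was at 3.08, 4.68 and 3.12 without aorta replicate 1, macrophage replicate 2 and macrophage replicate 3. In all, 48 miRNAs were detected in every aorta and in no macrophage sample, and 24 of them came from this region. Of the 48, 38 passed the threshold. No miRNA was detected in every macrophage sample and in no aorta. These counts used the limit of Ct 35 in every sample, although the mean Ct was later in macrophages (26.2 against 23.6). In aorta only and in macrophages only, the counts were 65 and 2 at Ct 28, and 42 and 0 at Ct 38. The count in macrophages only was 1 without aorta replicate 3, without macrophage replicate 1, or without aorta 3 and macrophage 3 together. miR-224, miR-485* and miR-384-5p were at least 945-fold, 655-fold and 594-fold lower, or 408-fold, 284-fold and 265-fold with quantile normalization. miR-708 was 286-fold lower. Leaving out macrophage replicate 2 gave -9.23 for miR-708, -9.34 for miR-434-3p, -10.58 for miR-376c, -11.39 for miR-127 and -9.28 for miR-376b*. Leaving out macrophage replicate 3 gave -7.33 for miR-708, -11.32 for miR-434-3p, -10.57 for miR-224, -10.04 for miR-485* and -9.90 for miR-384-5p. miR-376b* was at -10.87 without macrophage replicate 1, and miR-384-5p at -8.38 without aorta replicate 1.

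The direction of the miR-17~92 cluster and its paralogues, which promote cell division, depended on the scaling. Relative to the miRNA mean, 15 of 19 tested miRNAs were higher in macrophages, 1 was lower and 3 did not pass, or 16 and 1 adjusted over the list alone (camera, adjusted p = 0.000106, and adjusted p = 0.163 with an estimated correlation). The median difference was 1.95. With scaling to the snoRNA pair 3 were higher and 2 lower, with a median of -0.29, and without scaling none was higher and 1 was lower, with a median of -0.69. The counts were 8 and 1 with the deposited values, 6 and 1 with MammU6, and 17 and 0 with quantile normalization. Camera, which compares the list with the other miRNAs, gave an upward direction under every scaling, with a highest adjusted p of 0.00382 (without scaling). Scaling by 1 value per sample shifts all miRNAs alike, so it could hardly change that direction. The shared direction therefore does not tell whether the list was higher in macrophages than in aorta. With an estimated correlation the list missed the threshold under every scaling (adjusted p from 0.163 to 0.795). miR-18a was 27.2-fold higher (4.77 ± 0.46 SE), miR-17* was 25.3-fold higher and miR-19a*, detected in 1 aorta, was 24.4-fold higher. All 3 missed the threshold without scaling (adjusted p = 0.052, 0.182 and 0.174), and miR-19a* with the snoRNA pair (adjusted p = 0.117). The lower member, miR-20b*, detected in 1 macrophage sample, was at -4.07 (adjusted p = 0.0105, and -8.40 with the deposited values), and missed it with quantile normalization (adjusted p = 0.0627). miR-19a* was at 6.01 and 3.60 without macrophage replicates 1 and 3, and miR-20b* at -3.33 and -3.26 without aorta replicate 1 and macrophage replicate 2.

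The let-7 list counts main strands, which share a seed, together with star strands, which do not. It went both ways relative to the miRNA mean. Of 16 strands 6 were higher, 3 were lower and 7 did not pass (camera, adjusted p = 0.408, and 0.788 with an estimated correlation; 6 and 3 adjusted over the list alone). let-7a was 9.18-fold higher, miR-98 was 9.73-fold higher (3.28, and 3.92 without aorta replicate 3) and let-7i was 6.43-fold higher. The lower strands included the star strands let-7b* at -4.32 and let-7a* at -2.23. The counts thus do not show that strands with the same seed went opposite ways. The counts of higher and lower strands were 0 and 10 with scaling to the snoRNA pair (median -2.09), 0 and 7 without scaling (median -2.49), 1 and 3 with MammU6, 3 and 3 with the deposited values and 7 and 2 with quantile normalization, against a median of 0.15 in the main setting. With the snoRNA pair and without scaling let-7a, miR-98 and let-7i missed the threshold (adjusted p = 0.186, 0.221 and 0.368, and 0.707, 0.688 and 0.973). With MammU6 miR-98 and let-7i did (adjusted p = 0.0663 and 0.0564), and with the deposited values miR-98 did (adjusted p = 0.0576).

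**Figure D3:**
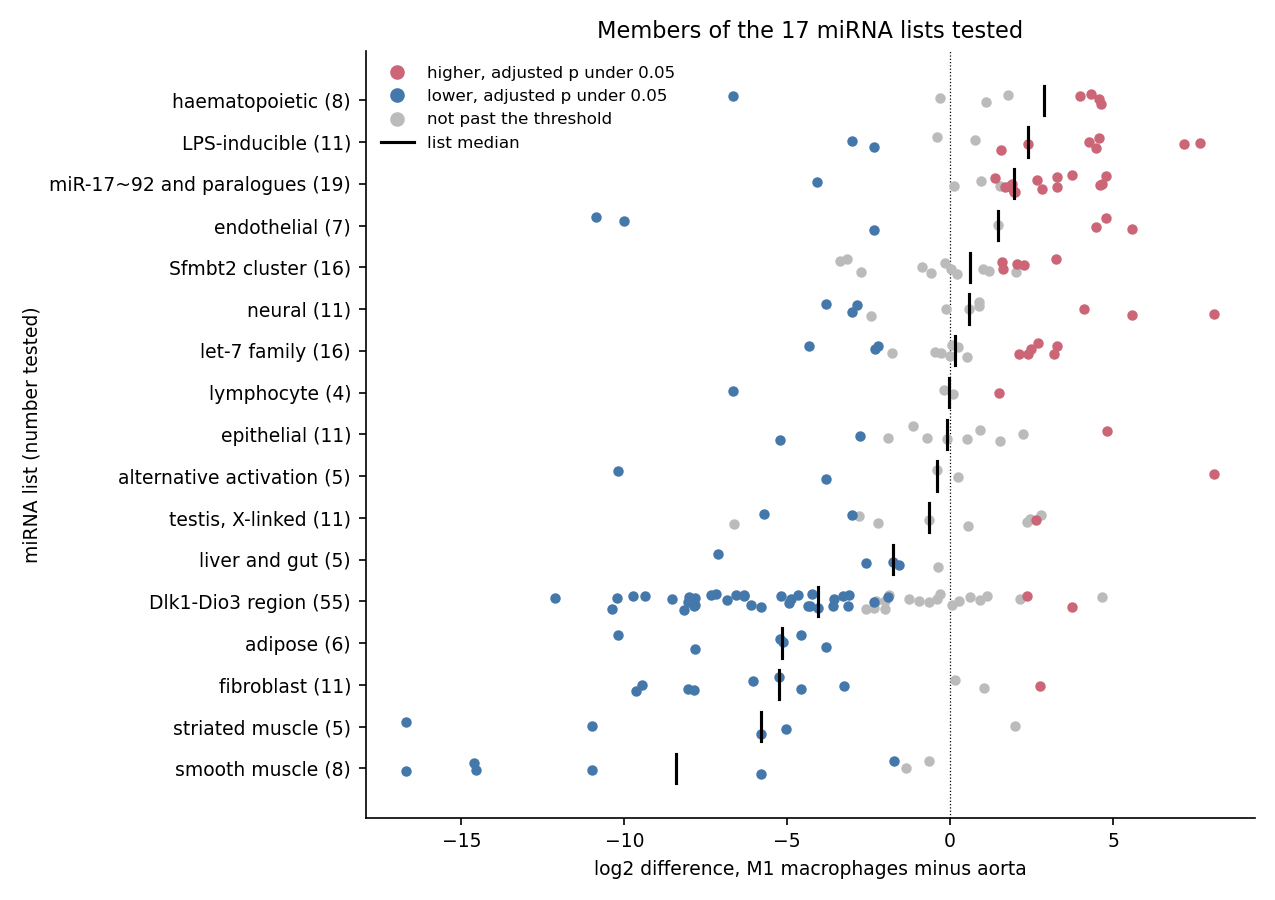
Each point is one tested miRNA of a list (vertical axis, with the number tested), placed by its log2 difference, macrophages minus aorta (horizontal axis). Red and blue points passed the threshold as higher or lower, grey points did not, and the black line is the list's median. The values are relative to the miRNA mean, and the medians of several lists change sign with the scaling. The smooth muscle median is -8.40 and the haematopoietic median is 2.88.

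Lists for other cell types did not pass. With the snoRNA pair the counts of higher and lower members were 0 and 4 for alternative activation, 1 and 6 for neural and 0 and 7 for epithelial miRNAs. Of 5 alternative activation miRNAs 1 was higher (miR-124) and 2 were lower (miR-193b and miR-378, 14.0-fold), with miR-125a-5p at -0.40 (adjusted p = 0.588, and 0.702 with an estimated correlation). Without macrophage replicate 3, miR-125a-5p was at 0.22, and with the snoRNA pair and without scaling it passed as lower (adjusted p = 0.0148 and 0.0383). Of 11 neural miRNAs 3 were higher and 3 lower (adjusted p = 0.588, and 0.814 with an estimated correlation). miR-7b was 17.3-fold higher, a call lost with scaling to the snoRNA pair (adjusted p = 0.054) and without scaling (adjusted p = 0.311). miR-137 was 14.0-fold lower, a call lost without aorta replicate 3 (adjusted p = 0.0652), without macrophage replicate 2 (adjusted p = 0.131) or 3 (adjusted p = 0.1199) and with quantile normalization (adjusted p = 0.0998). It was at -2.73, -4.52 and -4.57 without aorta replicate 1, aorta replicate 4 and macrophage replicate 1, against -3.80. Of 11 epithelial miRNAs 1 was higher (miR-141* at 4.81, and 3.59 without aorta replicate 3) and 2 were lower (miR-203 and miR-205). The miR-141* call was lost without macrophage replicate 3 (adjusted p = 0.0602), with the snoRNA pair (adjusted p = 0.146), with the deposited values (adjusted p = 0.0724) and without scaling (adjusted p = 0.127). miR-141 did not pass (adjusted p = 0.0844), except without aorta replicate 4 (adjusted p = 0.0455) and with quantile normalization (adjusted p = 0.00931). miR-205 was at least 6.74-fold lower, a call lost without macrophage replicate 1 or 2 (adjusted p = 0.0753 and 0.0803) and with quantile normalization (-0.79, adjusted p = 0.227), and at -3.44 without macrophage replicate 3. The epithelial list's adjusted p was 0.926, and 0.926 with an estimated correlation. Of 4 lymphocyte miRNAs miR-150 was lower, miR-181a was 2.82-fold higher, and miR-181c and miR-150* did not pass (list adjusted p = 0.926, and 0.926 with an estimated correlation). With scaling to the snoRNA pair miR-181a was at -0.74, and it missed the threshold with MammU6 (adjusted p = 0.424) and with the deposited values (adjusted p = 0.342). miR-181c passed as lower with the snoRNA pair (adjusted p = 0.00354) and without scaling (adjusted p = 0.0335), and miR-150* without scaling (adjusted p = 0.03196). Of 5 liver and gut miRNAs 4 were lower. miR-122 was at least 140-fold lower, or 57.4-fold with quantile normalization, miR-194 was 3.40-fold lower, miR-192 was 3.00-fold lower and miR-215 was 6.05-fold lower (list adjusted p = 0.167, and 0.641 with an estimated correlation). The miR-192 call was lost without macrophage replicate 1 (adjusted p = 0.0581) and with MammU6 (adjusted p = 0.0648). The miR-215 call was lost without aorta replicate 1 or 3 or macrophage replicate 1 (adjusted p = 0.0601, 0.0629 and 0.0951), with quantile normalization (adjusted p = 0.615) and with MammU6 (adjusted p = 0.0554). miR-215 was at -1.83 without macrophage replicate 1, against -2.60. miR-122 was at -6.09, -7.76 and -7.81 without aorta replicate 3, aorta replicate 4 and macrophage replicate 3, against -7.12. Counts adjusted over the list alone were the same for these 5 lists.

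The direction of the Sfmbt2 cluster also depended on the scaling. Relative to the miRNA mean, 5 of its 16 tested miRNAs were higher, or 3 adjusted over the list alone, and none was lower (adjusted p = 0.227, and 0.702 with an estimated correlation). With scaling to the snoRNA pair none was higher and 6 were lower, with a median of -1.63 against 0.61 in the main setting. The counts were 0 and 4 without scaling, 1 and 1 with the deposited values, 1 and 0 with MammU6 and 6 and 0 with quantile normalization. miR-467c was 9.45-fold higher, but at 1.00 with the snoRNA pair (adjusted p = 0.115) and 0.60 without scaling (adjusted p = 0.656). miR-466h, miR-466c-5p and miR-467e* did not pass, at -3.39, -3.15 and -2.75. They were detected in 1, 1 and 0 macrophage samples. With the snoRNA pair miR-466h and miR-467e* passed (adjusted p = 0.046 and 0.0295), as they did without scaling (adjusted p = 0.0336 and 0.01098), and miR-467e* also passed with the deposited values (adjusted p = 0.00573) and in further settings given in the closing section. Without macrophage replicate 2 miR-466h passed (adjusted p = 0.00108), and without aorta replicate 4 miR-467e* passed (adjusted p = 0.00631). Of 11 tested miRNAs of X-linked testis clusters 1 was higher and 2 were lower, with the same counts adjusted over the list alone (adjusted p = 0.926, and 0.926 with an estimated correlation). miR-547 was 52.5-fold lower and miR-743b-5p at least 8.15-fold lower, a call lost with quantile normalization (-0.89, adjusted p = 0.137), and was at -3.71 without macrophage replicate 3, against -3.03. miR-883a-3p and miR-883b-3p, seen in 3 aortas, did not pass, and miR-883a-3p passed as lower without aorta replicate 1 (adjusted p = 0.000739), with the snoRNA pair (adjusted p = 0.0377), with MammU6 (adjusted p = 0.0413) and without scaling (adjusted p = 0.019).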

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

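All tests weighed here were chosen, or had their bounds written, after the result was seen. An aorta far from the other aortas turned up in 2 of 83 results, where chance gives about 1 in 20. miR-685 was at -0.3 in aorta 2, with a median of -2.59 in the other aortas. miR-141* was at -8.45 in aorta 3, with a median of -3.57 in the others. The plant assay, which has no mouse target, crossed at Ct 21.1 in aorta 3, at 27.9 and 28.4 in aortas 1 and 2 and at 31.4 in macrophage replicate 3, and did not cross in the other 3 samples. Of the 238 calls, 66 had a mean Ct in their brighter group earlier than that earliest plant signal and 172 did not.

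The 238 differing miRNAs were tested against other splits of the samples. Only 1 of the 35 splits of the 7 samples into 4 and 3, the real one, gave as many, and the highest other gave 3. With 35 splits that share can be no smaller than 0.0286. Every other split also mixes aortas with macrophages within a group, so the real split stood alone but the test does not exclude chance. For the 6 lists past the threshold, 1 of 35 splits gave as many, but the highest other gave 5, so the number of lists separates the real split from others by a narrow margin. Strain stays open for both, since each strain has 1 sample type.

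Macrophage samples had fewer detected miRNAs. Lower RNA input as the whole cause is argued against by counts at equal depth, where the lowest aorta stayed above the highest macrophage sample by at least 41 miRNAs under 3 scalings. Depth was matched on a mean Ct per sample, that of MammU6 and snoRNA202, of the 296 shared miRNAs, or of the snoRNA pair. RNA input itself was not measured. Background later than Ct 28 in the aortas, alone or with lower input, is argued against as the whole cause by the following counts. At equal depth and limits no later than Ct 28, the gap was 30 miRNAs with MammU6 and snoRNA202 and 86 with the snoRNA pair. With the 296 shared miRNAs, the main scaling, it was 10, which is narrow. A part played by such background stays open, as does background at earlier cycles, since the plant assay crossed before Ct 28 in 2 aortas. The difference between tissue and cultured cells, and that of strain, was not tested.

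Background in late cycles may also enter the calls. Of the 202 calls whose brighter group had a mean Ct earlier than 28, 129 (63.9%) kept their direction and threshold at a limit of Ct 28. That lies below the 80% that would have argued against background and above the share that would have fitted it, so the test leaves it open. The stricter limit also truncates differences, which lowers the count without any background. In the later range 36 of 99 tested miRNAs were called (36.4%, 95% Wilson interval 27.6 to 46.2), against 61.2% in the earlier range, a comparison that does not decide the point because the limit at Ct 35 leaves less room for a difference in that range.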

How the results depend on the processing

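The replicate block, the scalings, the limits, the filters and leaving out each replicate were planned; the limit at Ct 28, leaving out early wells and leaving out aorta 3 and macrophage 3 together were chosen after seeing the data. No miRNA past the threshold passed in the opposite direction under any of these settings, and counts of differing miRNAs from 176 to 268 were found under all of them but the 2 named next. Among the named miRNAs, 1473 comparisons with an alternative kept direction and side of the threshold, 87 lost the threshold, 23 gained it and 23 changed sign. For lists the numbers were 349, 20, 17 and 21. Late wells limit the depth, and the alternative for fluorescence intensities was not run because the values are Ct. The cause was not tested for any change below, unless stated.

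At a limit of Ct 28, with fewer miRNAs tested, 148 differed and 53 were higher. Detection fell to a mean of 331.5 per aorta and 208 per macrophage sample (319 per macrophage sample at Ct 32), and r within macrophages was 0.88. The exact permutation per miRNA called 0 miRNAs, 0 higher and 0 lower, because 35 splits allow no smaller p than 0.0286, which 217 miRNAs reached. Higher calls numbered 32 with the snoRNA pair, 53 with the authors' deposited values, 52 with MammU6 and 10 without scaling. Lower calls numbered 231 with the snoRNA pair, 207 without scaling and 76 with detection in all 7 samples, which removes miRNAs absent from macrophages.

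With an estimated correlation the adjusted p was 0.163 for the adipose, fibroblast, miR-17~92 and smooth muscle lists, 0.269 for Dlk1-Dio3 and 0.218 for striated muscle, so no list passed. No list passed with an estimated correlation under any other setting either, and the lowest adjusted p was 0.0755 (Dlk1-Dio3, quantiles). Fry, which does not compare a list with other miRNAs, gave 0.00231 for the alternative activation, endothelial (lower, against higher) and lipopolysaccharide lists, 0.00618 for liver and gut, 0.0096 for lymphocyte, 0.0114 for haematopoietic and 0.0975 for epithelial miRNAs (lower, against higher). The fibroblast list missed the threshold with the deposited values (0.0526), detection in all 7 (0.13), the block (0.0564), Ct 28 (0.0589) and without aorta 3 and macrophage 3 (0.0539), and ranged from 0.00872 to 0.0549 without each replicate. Striated muscle missed it with the snoRNA pair (0.101), the deposited values (0.0804), detection in all 7 (0.303), no filter (0.0957), the block (0.0617) and Ct 28 (0.0558), and ranged from 0.0331 to 0.1004 without each replicate.

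The lipopolysaccharide list passed with the snoRNA pair (0.0192), the deposited values (0.0259), MammU6 (0.024), no scaling (0.0171) and Ct 38 (0.0487), and ranged from 0.0399 to 0.104 without each replicate. With an estimated correlation in these settings the adjusted p was 0.447, 0.433, 0.656, 0.795 and 0.443. The haematopoietic list passed with the snoRNA pair (0.0232), no scaling (0.0299), Ct 28 (0.021) and without aorta 3 and macrophage 3 (0.0262), and ranged from 0.0197 to 0.197. With an estimated correlation these were 0.419, 0.795, 0.305 and 0.332. For both lists a pass is relative to the other miRNAs tested and does not mean that the members were higher in macrophages. Without scaling no haematopoietic member was called higher.

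Lists far from the threshold changed sign. The endothelial list did so with quantiles (0.872), detection in all 7 (0.782) and no filter (0.937). The epithelial list did so with the snoRNA pair (0.757), the deposited values (0.896) and no filter (0.937), with a range of 0.772 to 0.981 without each replicate. Testis miRNAs did so with the snoRNA pair (0.647), quantiles (0.872), the deposited values (0.896), MammU6 (0.864), no scaling (0.774), Ct 32 (0.631), detection in all 7 (0.891) and no filter (0.432), with a range of 0.813 to 0.981. The lymphocyte list did so with quantiles (0.872) and Ct 38 (0.958).

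Named miRNAs and reference RNAs changed sign as follows, on the log2 scale. With the snoRNA pair miR-141 was at -0.008, miR-181a at -0.74, miR-150* at -2.16, miR-342-5p at -0.46 and snoRNA202 at -0.91, where the last is fixed by the scaling itself, since snoRNA202 is part of the pair. Without scaling they were at -0.41, -1.14, -2.56, -0.87 and -1.31. miR-150* was at -0.91 with the deposited values, -0.57 with MammU6, -0.30 with the block, -0.21 at Ct 32 and -0.46 without aorta 3 and macrophage 3, where miR-125a-5p was at 0.023 and miR-181c at 0.003. miR-181c was at 0.62 with quantiles. miR-20b was at -0.29 with the snoRNA pair and -0.69 without scaling, and miR-494 was at -0.29 without scaling. MammU6 was at -1.58 with the snoRNA pair, -1.98 without scaling and -0.34 with the deposited values, against 0.66, and U87 at -0.44 with the snoRNA pair and -0.84 without scaling, against 1.80. snoRNA429 was at 0.025 with the median, against -0.05. At Ct 28 miR-20b* was at 0.57 and miR-466h at 0.25. Without each replicate miR-125a-5p ranged from -0.85 to 0.22, miR-181c from -0.29 to 0.089 and miR-150* from -0.31 to 0.42.

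Other calls of named miRNAs were lost or gained, beside those in the report. miR-124 missed the threshold also at Ct 28 and Ct 38, with no filter, the trend, the block, early wells left out and without aorta 3 and macrophage 3. Without that pair of samples miR-137, miR-147, miR-192 and miR-215 missed it and miR-342-5p passed. At Ct 28 miR-122, miR-137, miR-181a, miR-206 and miR-486 missed it and miR-342-5p passed. At Ct 32 miR-20b*, miR-205, miR-215, miR-486 and miR-743b-5p missed it. At Ct 38 miR-137 missed it and miR-467e* passed. With the block miR-141*, miR-181a, miR-205, miR-215 and miR-743b-5p missed it, and miR-141 and miR-467e* passed.

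The replicate block gave 212 differing miRNAs, 91 higher and 121 lower, and 202 of the main calls were kept. Of the 75 named miRNAs 6 lost the threshold with it, 2 gained it and 1 changed sign. Samples of one number deviated with correlations of 0.11, 0.008 and -0.074. These give no sign that the numbers pair the samples, but so few values cannot exclude it.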

Other observations

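The tests in this part were chosen after the results were seen, except the test of neighbouring precursors, whose bounds were written before it was run; the pool it re-draws from was narrowed afterwards. The lists named here were added after the data were seen. The miR-30 family was mostly lower in macrophages, with 7 of 10 strands lower and none higher. miR-30a* fell by 5.70 ± 0.40 SE on the log2 scale and miR-30c by 1.99 ± 0.35 SE, while miR-30a and miR-30d did not pass. As a list it missed the threshold (camera, adjusted p = 0.116, and adjusted p = 0.427 with an estimated correlation). In the miR-130 and miR-301 family, miR-130b was higher at 5.14 ± 0.58 SE (a call lost without scaling, adjusted p = 0.0743) and miR-130a lower at -3.85 ± 0.57 SE (list adjusted p = 0.393). Other added lists did not pass. The adjusted p was 0.595 for the miR-15 and miR-16 family, 0.513 for miR-23, miR-27 and miR-24, 0.393 for the miR-322 and miR-503 cluster, 0.518 for embryonic stem cell miRNAs and 0.98 for the miR-183 cluster.

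Strands and neighbours of one transcript may move together, as they would if the difference lay mainly in transcription. Over 108 hairpins with both strands tested, the strands' differences correlated across hairpins (Pearson's r = 0.557, permutation p = 1e-05, Spearman's rho = 0.611, permutation p = 1e-05, the smallest p that 100000 permutations can give). Hairpins of one cluster are not independent, so these p are too small. The differences of the 2 strands had the same sign for 74 of the 108 hairpins (68.5%). That share can move with the scaling, which shifts all differences, and no share for re-paired hairpins is given beside it. Both strands were called in one direction for 35 hairpins and in opposite directions for 2, let-7a (let-7a at 3.20, let-7a* at -2.23) and miR-20b (1.95, and -4.07 for miR-20b*). With scaling to the snoRNA pair neither let-7a (adjusted p = 0.186) nor miR-20b (-0.29, adjusted p = 0.685) passed, so these opposite calls depend on the scaling. That scaling shifts both strands of a hairpin alike, so it leaves the difference between the strands unchanged. For 54 pairs of neighbouring precursors within 10 kb outside the Dlk1-Dio3 region, the mean absolute difference between neighbours was 1.79 against 4.11 for re-drawn pairs (permutation p = 1e-04, the smallest that 10000 can give). The neighbours had the same sign in 64.8% of these pairs, a share that can also move with the scaling. Pairs within one cluster are not independent, so the permutation p may be too small. Assays that pick up near-identical members of one cluster would also give a small mean difference, and this was not separated.

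Assays without a miRNA gene in RefSeq may be called higher more often. Of 9 such assays tested 4 were higher, against 102 of 420 others (24.3%), and Fisher's exact test, 2-sided, gave p = 0.234, so the question stays open at this number of assays.

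Macrophage replicate 3 differed from the mean of the other macrophage samples by -1.88 for miR-155 and -2.63 for miR-146a, where the SD over 313 miRNAs was 1.36. Of the 11 lipopolysaccharide-inducible miRNAs 8 were lower in it and 3 were higher, miR-147 by 2.04, miR-9 by 1.71 and let-7e by 0.25. A weaker response to lipopolysaccharide in that culture is a candidate explanation, but the test leaves it open. The median deviation of the 11 lipopolysaccharide-inducible miRNAs was -0.65, at the 3.9th percentile of 10000 random lists matched on mean level. The percentile depended on how random lists were drawn: it was 2.4 without matching and 14.0 when matched lists could repeat a miRNA. Of 23 lists compared in this way, 0 lay under the 2.5th percentile with matching. The neural list lay at 4.2, alternative activation at 5.4, smooth muscle at 5.6 and Sfmbt2 at 6.1. At the other end the endothelial and miR-17~92 lists lay at 97.0 and the miR-183 cluster at 98.1. A low position was thus not particular to the lipopolysaccharide list. Macrophage replicate 3 also had the latest mean Ct, at 27.8.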
